A study of Homo sapiens with 36 samples.

How the data were processed

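RNA sequencing counts were used from 36 libraries of hemato-endothelial precursors sorted on day 15 from embryoid bodies of the human embryonic stem cell line AND1, 9 each with an empty vector (control), AF4-MLL, MLL-AF4 or both fusions. Per the labels, cDNA was made by the SMART-seq2 protocol, libraries were prepared with the Nextera XT kit, which does not mark the strand, and sequencing was done on a HiSeq 4000. The deposited values are raw read counts per gene, per the file name and the submitters' processing notes, which name STAR 2.4.2a, HTSeq 0.5.3p3 and the genome builds hg19 and GRCh37. The values were whole numbers with no further normalisation by the authors. The annotation release and the strand setting of the counting are not stated.

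The table held 65988 gene identifiers and 57107856 counts, with 0 summary lines and 0 columns left unused. A count was present for 33891 identifiers. Symbols came from a table of gene names that held 56434 of the identifiers and from GENCODE release 29, which held 56927 of them and 99.956% of the counts. Since that release describes a later genome build than the one named by the submitters, chromosome names are given without positions.

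The replicate was set by the sample number in the library titles: counts of the 3 libraries that share a group and a sample number were summed, giving 3 replicates per group and 12 in all. This was checked with the chi-square dispersion of counts between libraries of a group, per degree of freedom: its median was 12.2 between libraries that share the sample number and 18.7 between libraries that share the repeat number. Neither kind agreed within sampling noise, and the sample number was kept, as set before the data were examined. The comparisons, the tests, the gene lists and the rule for named genes were also fixed before the data were examined. So were the alternatives for gene counts and named genes that leave out replicates or change the normalisation, filter, tool or replicate unit.

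Genes were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter of filterByExpr (minimum count 10, minimum total count 15) left 14408 genes. Counts were normalised by TMM (factors 0.884 to 1.05), and the 4 groups were fitted together with the quasi-likelihood method (glmQLFit and glmQLFTest, two-sided, prior count 2). The common dispersion was 0.343. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each pair of groups was compared, and an interaction contrast (both fusions minus AF4-MLL minus MLL-AF4 plus control) tested whether the combined change differed from the sum of the single changes. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM are normalised counts of the summed replicates, scaled to the library total, with SD over 3 replicates. A fold against a group with 0 counts was computed from counts pooled over each group, against a floor of 3 counts over the group, and a ratio with 3 counts or fewer is given with a 95% counting interval.

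The 25 gene lists held 646 symbols, of which 1 (EXOC3L2) was not matched. The lists were hematopoietic transcription factors and hemogenic endothelium, pan-endothelial, arterial, and venous and lymphatic endothelium, HOX genes and MLL-fusion targets, MLL and AF4 complexes, Notch signalling and Wnt signalling. Further lists were cell cycle, p53 targets with cell cycle inhibitors and apoptosis, epithelial-mesenchymal and endothelial-mesenchymal transition, interferon response, immediate early and heat shock, glycolysis and hypoxia, oxidative phosphorylation, and extracellular matrix and basement membrane. Markers of cells that the sort could also hold were erythroid, megakaryocyte, myeloid, lymphoid, pluripotent, mesenchymal, smooth muscle and cardiac, epithelial and endodermal, and neural. Lists were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 25 lists of a comparison. Camera compares the list with all other genes, and fry tests whether the genes of a list move on balance in a single direction. Members were counted as passing over all genes and when adjusted over the list alone.

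Named genes were KMT2A and AFF1, and, for both fusions against control, the 10 genes with the largest rise and the 10 with the largest fall among genes that passed, had a symbol and at least 10 CPM in the higher group, and showed no overlap of replicates, pseudogenes left out. For the other comparisons and the interaction, 5 and 5 were named by the same rule, with no overlap condition for the interaction. From each list described, up to 4 members that passed or the 2 with the smallest p were named. GBP4, ARMCX1, HIF1A and CAMTA1 were named after their values were seen, because each completes a set of 7 genes.

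The alternatives were DESeq2 size factors or upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no low-count filter or a filter of 10 CPM in 3 replicates, and the 36 libraries as separate samples. Further alternatives were the 36 libraries with the sample number as a random effect, sums by repeat number, the sample number as a block, only the groups compared in the fit, leaving out libraries under 0.2 of the median total, and leaving out each replicate in turn. Leaving out libraries with fewer than 13000 genes detected, and leaving out each replicate in turn in the gene list tests, were added after the data were seen. The pipeline was tested on simulated data made from these libraries. In 5 draws with 13896 genes, edgeR found 2.8% of genes changed 2-fold, 42% of those changed 4-fold, 76.8% of those changed 8-fold and 90.8% of those changed 16-fold. Of 551 calls, 20 (3.63%) were of genes that had not changed. Camera called 0 of 125 random lists, and 0 genes were called where none had changed. The changed genes were drawn from the more abundant genes, and counts were drawn independently between genes. The simulation therefore could not test camera on genes that move together. Every group was given the same dispersion per gene. In the data, the chi-square dispersion between libraries of a sample number reached 58.5 with both fusions and 20.1 with MLL-AF4. The simulated share of false calls therefore need not hold for the real comparisons.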

Results

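The data were RNA sequencing counts of hemato-endothelial precursors, the embryonic precursors of blood and vessel-lining cells, sorted on day 15 from embryoid bodies of the human embryonic stem cell line AND1. The cells carried an empty vector (control), AF4-MLL, MLL-AF4 or both fusions, the 2 reciprocal products of the rearrangement that joins the MLL gene (KMT2A) to AF4 (AFF1) in infant leukemia. Each of the 4 groups held 9 libraries, named by 3 sample numbers with 3 libraries each. The libraries of a sample number were summed to a replicate (n = 3 per group, 12 replicates and 36 libraries in all). The labels call the assay single-cell RNA sequencing, while the protocol states 3 independent replicates of 50 cells per condition. Nothing beyond that wording states that the replicates are separate cultures. The labels also name no separate lines within a group. In every comparison below, an effect of a fusion therefore cannot be told apart from a difference between lines. The p-values measure the spread between replicates of a group and not between independently made lines.

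Library totals ran from 231357 to 3610519 counts, with a median of 1535740. They ran from 265152 to 3447668 in control, from 231357 to 3610519 with AF4-MLL, from 1094762 to 2317381 with MLL-AF4 and from 312902 to 2052765 with both fusions. Summed over its 3 libraries, a replicate held between 1345580 counts (AF4-MLL replicate 3) and 8156288 counts (control replicate 2). The median library detected 15454 genes in control, 16444 with AF4-MLL, 16273 with MLL-AF4 and 13330 with both fusions. Ribosomal protein genes took a median of 7.02% of counts in control, 8.07% with AF4-MLL, 8.21% with MLL-AF4 and 5.09% with both fusions. With both fusions, this share was 2.95% to 5.67% in the libraries of replicates 1 and 3 and 7.63% to 9.69% in those of replicate 2. Mitochondrial genes took a median of 9.36% of counts in control, 12.6% with AF4-MLL, 13.9% with MLL-AF4 and 11.8% with both fusions. Intervals and floors given below cover counting error only, since reads amplified by PCR are not independent molecules.

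**Figure D1:**
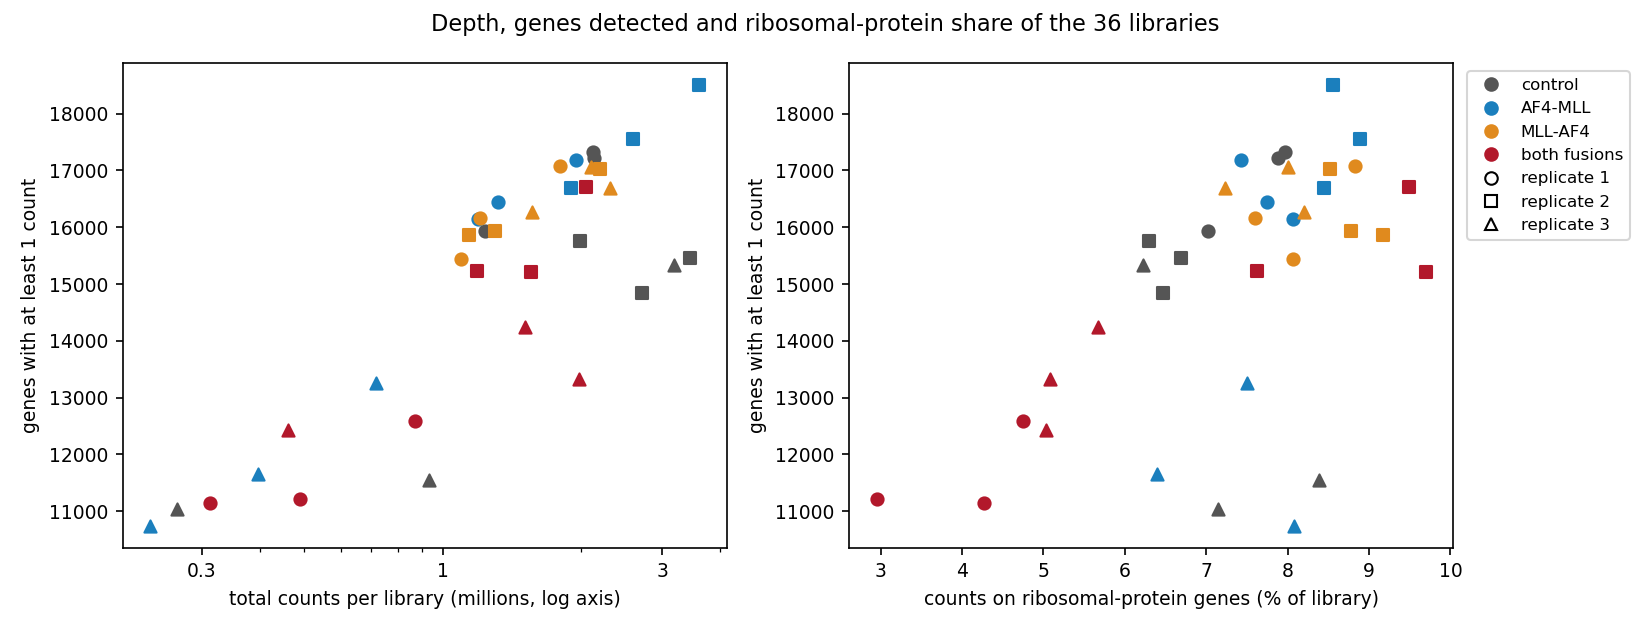
Total counts per library (log axis, left) and the percentage of counts on ribosomal protein genes (right) against the number of genes detected, for 36 libraries coloured by group and shaped by replicate. The libraries of both-fusions replicates 1 and 3 lie between 2.95% and 5.67% ribosomal protein counts, below those of replicate 2.

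KMT2A and AFF1, the partner genes on which reads of the fusion transgenes could fall, did not differ between any groups. KMT2A (ENSG00000118058, chromosome 11), a histone methyltransferase gene, stood at 90.7 ± 25.3 CPM (normalised counts scaled to the library total; mean ± SD of 3 replicates) in control, 98.5 ± 31.8 with AF4-MLL, 93.0 ± 10.2 with MLL-AF4 and 119.9 ± 37.1 with both fusions. AFF1 (ENSG00000172493, chromosome 4), a gene of the super elongation complex, stood at 50.2 ± 2.22, 64.1 ± 8.72, 69.9 ± 11.9 and 63.4 ± 39.0 CPM. Against control, the KMT2A log2 fold change was 0.40 (SE 0.322, adjusted p = 0.698) with both fusions, 0.13 (adjusted p = 1) with AF4-MLL and 0.04 (adjusted p = 0.999) with MLL-AF4. For AFF1 it was 0.35 (SE 0.389, adjusted p = 0.793), 0.35 (adjusted p = 1) and 0.48 (adjusted p = 0.999). These counts therefore do not check the group labels. The sign of several of these small differences turned when 1 replicate was left out. AFF1 with both fusions was -0.22 without both-fusions replicate 3, and KMT2A with AF4-MLL was -0.11 without AF4-MLL replicate 1. KMT2A with MLL-AF4 was -0.07 and -0.08 without control replicates 2 and 3 and -0.03 without MLL-AF4 replicate 1.

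The comparison of both fusions with control asked what the combined expression of the 2 fusions, the contrast the series design names, changed in these precursors. With both fusions, 4 genes rose and 34 fell among 14408 tested, and all 38 changed 2-fold or more with no overlap of replicates. The genes that fell included CAT (catalase), S100A6 (a calcium-binding protein), CSRP1 (a LIM-domain protein of the actin cytoskeleton), APLNR (the apelin receptor of endothelial cells) and EYA4 (a transcriptional coactivator with phosphatase activity). The genes that rose included SLC40A1 (ferroportin, the cellular iron exporter), from 48.7 ± 18.2 to 509.9 ± 267 CPM, and SPINT2 (a Kunitz-type protease inhibitor), from 29.5 ± 6.63 to 180.0 ± 104 CPM.

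EYA4 (ENSG00000112319, chromosome 6) stood at 165 ± 85.2 CPM in control and had 0 counts in all 9 both-fusions libraries. With the counts of each group pooled over its libraries, it was at least 616-fold lower against a floor of 3 counts over the group (0.298 CPM), with an adjusted p of 0.00014. S100A6 (ENSG00000197956, chromosome 1) fell from 103 ± 15.7 to 5.06 ± 3.57 CPM, a log2 fold change of -4.46 (SE 0.488, adjusted p = 0.00137). CAT (ENSG00000121691, chromosome 11) fell from 47.1 ± 27.6 to 1.40 ± 0.903 CPM, a log2 fold change of -5.19 (SE 0.58, adjusted p = 0.00137). CSRP1 (ENSG00000159176, chromosome 1) fell from 285 ± 129 to 6.26 ± 6.90 CPM, a log2 fold change of -5.43 (SE 0.636, adjusted p = 0.00178). ZNF667-AS1 (ENSG00000166770, chromosome 19), annotated as a long noncoding RNA, fell by 5.23 on the log2 scale (adjusted p = 0.00296), and DUSP23 (ENSG00000158716, chromosome 1), a dual-specificity phosphatase, fell by 4.25 (adjusted p = 0.00298). SMTNL1 (ENSG00000214872, chromosome 11) fell by 5.62 (adjusted p = 0.00884), and NNAT (ENSG00000053438, chromosome 20), an imprinted gene with 20.43, 25.78 and 432 CPM in control replicates 1, 2 and 3, fell by 6.96 (SE 1.18, adjusted p = 0.0252). Without control replicate 3, NNAT stood at -4.185 and SMTNL1 at -4.39, both still called. LAMC3 (ENSG00000050555, chromosome 9), a laminin chain, fell by 4.05 (adjusted p = 0.0407), and SYT11 (ENSG00000132718, chromosome 1), a synaptotagmin, fell by 4.02 (adjusted p = 0.0360). Among the genes that rose, the log2 fold change was 3.39 (SE 0.575, adjusted p = 0.0252) for SLC40A1 (ENSG00000138449, chromosome 2) and 2.60 (SE 0.486, adjusted p = 0.0420) for SPINT2 (ENSG00000167642, chromosome 19). CCDC144NL-AS1 (ENSG00000233098, chromosome 17) rose by 3.41 (SE 0.601, adjusted p = 0.0309). The libraries do not mark the strand, so reads of the antisense genes ZNF667-AS1 and CCDC144NL-AS1 cannot be separated from those of their opposite strand, in this and every other comparison. DPP4 (ENSG00000197635, chromosome 2), a cell-surface dipeptidase, rose with an adjusted p of 0.0429: it held 2 counts in control and counts in 5 of 9 both-fusions libraries, a pooled ratio of 181 with a 95% counting interval of 49.6 to 1510. Both-fusions replicate 3 held 162 of the 197 DPP4 counts of its group (39.43 CPM, against 13.18 and 2.84 in replicates 1 and 2), and without it the log2 fold change was 5.766, against 7.02, and was not called.

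**Figure D2:**
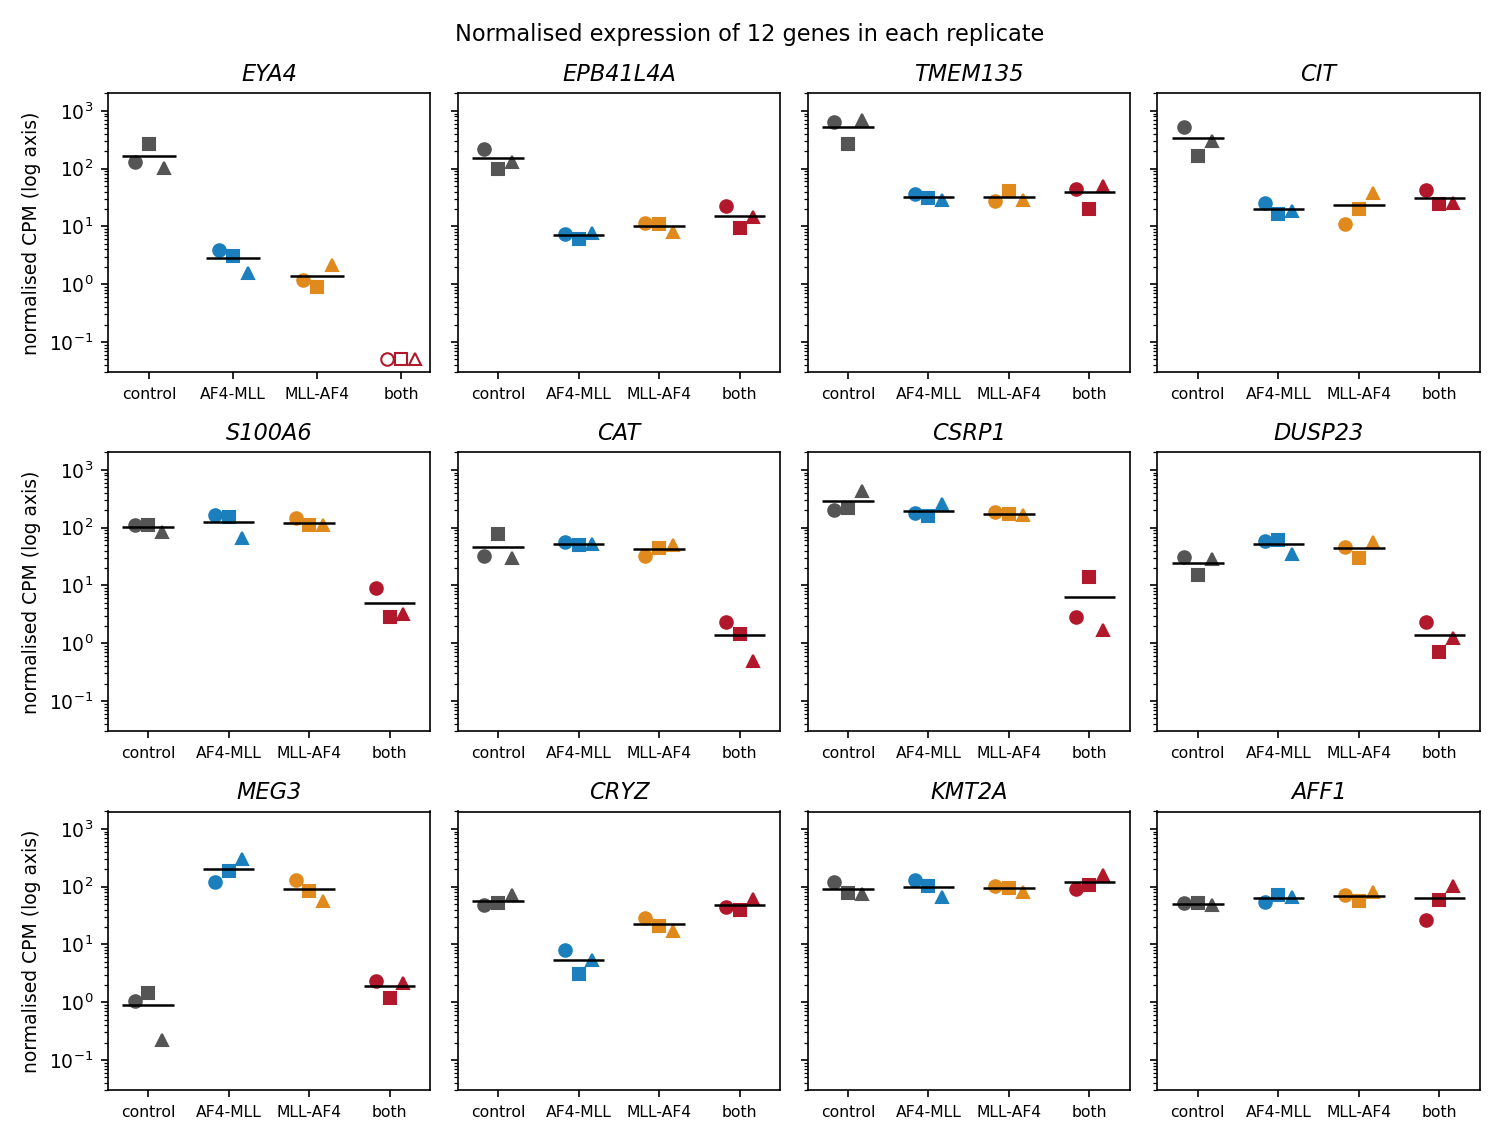
Normalised CPM (log axis) of 12 genes in the 3 replicates of each group, as points with a line at the group mean, and with values of 0 drawn as open points at 0.05. EYA4, EPB41L4A, TMEM135 and CIT are high in control alone, S100A6, CAT, CSRP1 and DUSP23 are low with both fusions alone, and MEG3 is high with each fusion alone.

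The test of both fusions against control was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 it called 1572 genes (10.9%), and the replicates of the 2 groups did not overlap in 11% of all genes, where chance gives 10%. The count rested on single replicates: it was 17 without control replicate 1, 22 without control replicate 3, 17 without both-fusions replicate 3 and 127 without both-fusions replicate 2. It was 24, of which 19 were among the 38, without libraries that detected fewer than 13000 genes, which left 2 both-fusions replicates, and 1 (EYA4) when the single-fusion groups were left out of the fit. DESeq2 called 423 genes and limma-voom 15.

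Several of these calls ended without a single replicate. That of DPP4 ended without each control replicate (adjusted p up to 0.142) and without both-fusions replicate 1 (0.0565) or 3 (0.135). SLC40A1 lost its call without control replicate 1 (0.121), 2 (0.0532) or 3 (0.109) and without both-fusions replicate 3 (0.0866). SPINT2 lost it without control replicate 1 (0.124), 2 (0.110) or 3 (0.172) and without both-fusions replicate 1 (0.0993), and CCDC144NL-AS1 without control replicate 1 (0.121) or 2 (0.0560) and without both-fusions replicate 3 (0.1). LAMC3 and SYT11 lost theirs without each control replicate (up to 0.136 and 0.0872) and without both-fusions replicate 1 (0.0851 and 0.0779) or 3 (0.118 for each). NNAT lost its call without both-fusions replicate 1 (0.0674) or 3 (0.118), APLNR without replicate 1 (0.0508) or 3 (0.0637), and SMTNL1 (0.0637) and TFPI2 (0.0675) without replicate 3. Those of EYA4, CAT, S100A6, CSRP1, ZNF667-AS1 and DUSP23 stayed in all 6 fits that left out 1 replicate of these groups. With limma-voom the calls of CAT (0.107) and DUSP23 (0.156) ended, with the sample number as a random effect that of DUSP23 (0.0566), and with only the 2 groups in the fit those of all of these but EYA4 (0.143 to 0.314). Other genes gained a call: TEK without control replicate 2 (0.024), TGFBI (0.0436), APOB (0.0394) and HNF4A (0.0427) without both-fusions replicate 2, and BMP4 without both-fusions replicate 3 (0.041). Without libraries under 13000 genes detected, the calls of DPP4 (0.0728), SPINT2 (0.0938), SMTNL1 (0.055), LAMC3 (0.186), SYT11 (0.347), TFPI2 (0.134) and APLNR (0.0724) ended.

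Values given for members of gene lists are log2 fold changes. Of 25 gene lists, camera placed 4 higher and 5 lower with both fusions than in control. None of these calls held with an estimated correlation between genes (lowest adjusted p = 0.374), and of the 25 lists fry called the venous and lymphatic list alone. The number of called lists was 5 without both-fusions replicate 2. The lowest adjusted p was that of markers of epithelial and endodermal cells: 16 of 17 measured genes were higher, with a median log2 fold change of 2.81 (25th to 75th percentile 1.68 to 3.53). None passed over all genes, while 7 rose and none fell when adjusted over the list alone (camera adjusted p = 6.48e-06, and adjusted p = 0.503 with an estimated correlation). APOB, an apolipoprotein of liver and yolk sac, had a log2 fold change of 5.75 (SE 1.40, adjusted p = 0.148), and HNF4A, a transcription factor of endoderm, 6.13 (SE 1.55, adjusted p = 0.173). The summed level of this list was 4932, 790 and 3791 CPM in both-fusions replicates 1, 2 and 3, and 630.4, 341 and 586 CPM in control. Its higher replicates, 1 and 3, were those with the lowest ribosomal protein share. The list stayed called in all 6 fits that left out 1 replicate (highest adjusted p 0.00302). Without both-fusions replicate 3, APOB stood at 2.439.

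Of the endothelial lists, camera placed the venous and lymphatic and the pan-endothelial lists lower with both fusions and did not call the arterial list. In the venous and lymphatic list, TFPI2 (a Kunitz-type protease inhibitor) and APLNR fell, with log2 fold changes of -3.41 (SE 0.517) and -3.19 (SE 0.491) and an adjusted p of 0.0109 each. The other 13 of 15 measured genes did not pass. Adjusted over the list alone, 2 rose and 7 fell (median -1.09, camera adjusted p = 0.00955, adjusted p = 0.374 with an estimated correlation, fry adjusted p = 0.0268). Of the 33 measured pan-endothelial genes none passed over all genes, 1 fell when adjusted over the list alone, and 26 were lower (median -0.70, camera adjusted p = 0.00162, adjusted p = 0.842 with an estimated correlation). TEK, the angiopoietin receptor, had a log2 fold change of -1.70 (SE 0.408, adjusted p = 0.144) and CALCRL, a receptor of adrenomedullin, -1.71 (SE 0.552, adjusted p = 0.285). The venous call ended without both-fusions replicate 2 (adjusted p = 0.104), and the pan-endothelial call without both-fusions replicate 2 (0.481) or control replicate 3. The pan-endothelial list summed to 6235, 3183 and 6669 CPM in both-fusions replicates 1, 2 and 3, against 6523, 4711 and 13680 CPM in control. Both-fusions replicate 2 also held the most erythroid (53670 CPM) and megakaryocyte (10480 CPM) markers of its group. Without control replicate 3, CALCRL stood at -0.8172.

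Megakaryocyte markers were higher: 13 of 15 measured genes, with a median of 2.06, none passing over all genes, and 4 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.842 with an estimated correlation). PPBP, a platelet chemokine, had a log2 fold change of 6.08 (SE 1.75, adjusted p = 0.221) and SELP, P-selectin of platelets and endothelium, 3.62 (SE 1.02, adjusted p = 0.221). The summed level of the list was 778 CPM, 10480 CPM and 2925 CPM in both-fusions replicates 1, 2 and 3, against 945 to 1755 CPM in control. The call ended without both-fusions replicate 2 (0.739), where PPBP stood at 1.61, or control replicate 1. Erythroid markers, not called (adjusted p = 0.505), summed to 1716, 53670 and 1470 CPM in both-fusions replicates 1, 2 and 3, and to 14170, 10800 and 4494 CPM in control. Lymphoid markers were lower in 7 of 8 measured genes (median -1.21, none passing over all genes or when adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.374 with an estimated correlation). IL7R stood at -3.76 (SE 1.39, adjusted p = 0.333) and RAG1 at -4.31 (SE 1.75, adjusted p = 0.385). This call ended without both-fusions replicate 3 (0.143), and RAG1 stood at -7.875 without replicate 1. Levels were low: over its 22 genes the lymphoid list summed to 11.44 to 51.36 CPM with both fusions and 57.03 to 123.6 CPM in control. Mesenchymal markers were lower in 12 of 16 (median -1.01, none passing over all genes, 3 fell when adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.729 with an estimated correlation). THY1 stood at -2.19 (SE 0.583, adjusted p = 0.195) and NT5E at -2.22 (SE 0.661, adjusted p = 0.241). This call ended without both-fusions replicate 1 or 3 or control replicate 1 (0.231), and THY1 stood at -1.327 without control replicate 3.

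Cell cycle genes were higher in 30 of 40 (median 0.40), with none passing over all genes or when adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.842 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitosis, had a log2 fold change of 1.27 (SE 0.368, adjusted p = 0.221) and BUB1, a spindle checkpoint kinase, 1.31 (SE 0.439, adjusted p = 0.298). The list of p53 targets, cell cycle inhibitors and apoptosis genes was higher in 20 of 24 (median 0.62), with none passing over all genes and 1 that rose when adjusted over the list alone (camera adjusted p = 0.00756, adjusted p = 0.503 with an estimated correlation). Its members BCL2L1, an inhibitor of apoptosis, and BTG2, an antiproliferative p53 target, had values of 1.29 (SE 0.315, adjusted p = 0.148) and 1.17 (SE 0.482, adjusted p = 0.390). The summed level of the p53 list was 1702, 854.9 and 1131 CPM in both-fusions replicates 1, 2 and 3, against 806.2 to 877.9 CPM in control. Replicates 1 and 3 were those with the lowest ribosomal protein share and the higher epithelial and endodermal markers. Genes of epithelial-mesenchymal and endothelial-mesenchymal transition were lower in 19 of 24 (median -0.58, none passing over all genes or when adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.729 with an estimated correlation). TGFBI stood at -2.60 (SE 0.812, adjusted p = 0.262) and BMP4 at -2.09 (SE 0.805, adjusted p = 0.359). TGFBI stood at -4.183 without both-fusions replicate 2, and BMP4 at -4.245 without both-fusions replicate 3 and at -1.393 without control replicate 3. The transition list summed to 3128, 1231 and 3584 CPM in both-fusions replicates 1, 2 and 3, against 2545 to 5185 CPM in control, and the cell cycle list to 5438, 8079 and 7738 CPM, against 5072, 7555 and 2719 CPM in control. Without both-fusions replicate 2 the cell cycle call and the transition call (0.541) ended, as did the former without control replicate 3 (0.626) and the latter without control replicate 1, while the p53 call ended without both-fusions replicate 1 (0.293).

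The other 16 lists were not called. HOX genes and MLL-fusion targets had an adjusted p of 0.179 (median -0.26, none of 33 passing over all genes, 1 rose and 3 fell when adjusted over the list alone). HMGA2, a chromatin protein, stood at -2.53 (SE 0.524, adjusted p = 0.0715) and HOXA13 at -3.23 (SE 0.877, adjusted p = 0.204). Hematopoietic transcription factors and hemogenic endothelium had an adjusted p of 0.659 (median 0.33, none of 30 passing), with ITGA2B, the platelet integrin chain, at 2.29 (SE 0.705, adjusted p = 0.258) and GFI1, a transcriptional repressor, at -3.31 (SE 1.44, adjusted p = 0.422). Without both-fusions replicate 2, ITGA2B stood at 1.275 and GFI1 at -9.562, and without control replicate 3, HOXA13 stood at -1.507. The adjusted p was 0.321 for arterial endothelium, 0.884 for MLL and AF4 complexes, 0.248 for Notch signalling, 0.779 for Wnt signalling, 0.179 for the interferon response and 0.619 for immediate early and heat shock genes. It was 0.841 for glycolysis and hypoxia, 0.861 for oxidative phosphorylation, 0.884 for extracellular matrix and basement membrane, 0.659 for myeloid, 0.747 for pluripotent, 0.538 for smooth muscle and cardiac and 0.659 for neural markers. The median, mean and test differed in sign for the lists of MLL and AF4 complexes, Wnt signalling, extracellular matrix, erythroid, pluripotent and neural genes.

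**Figure D3:**
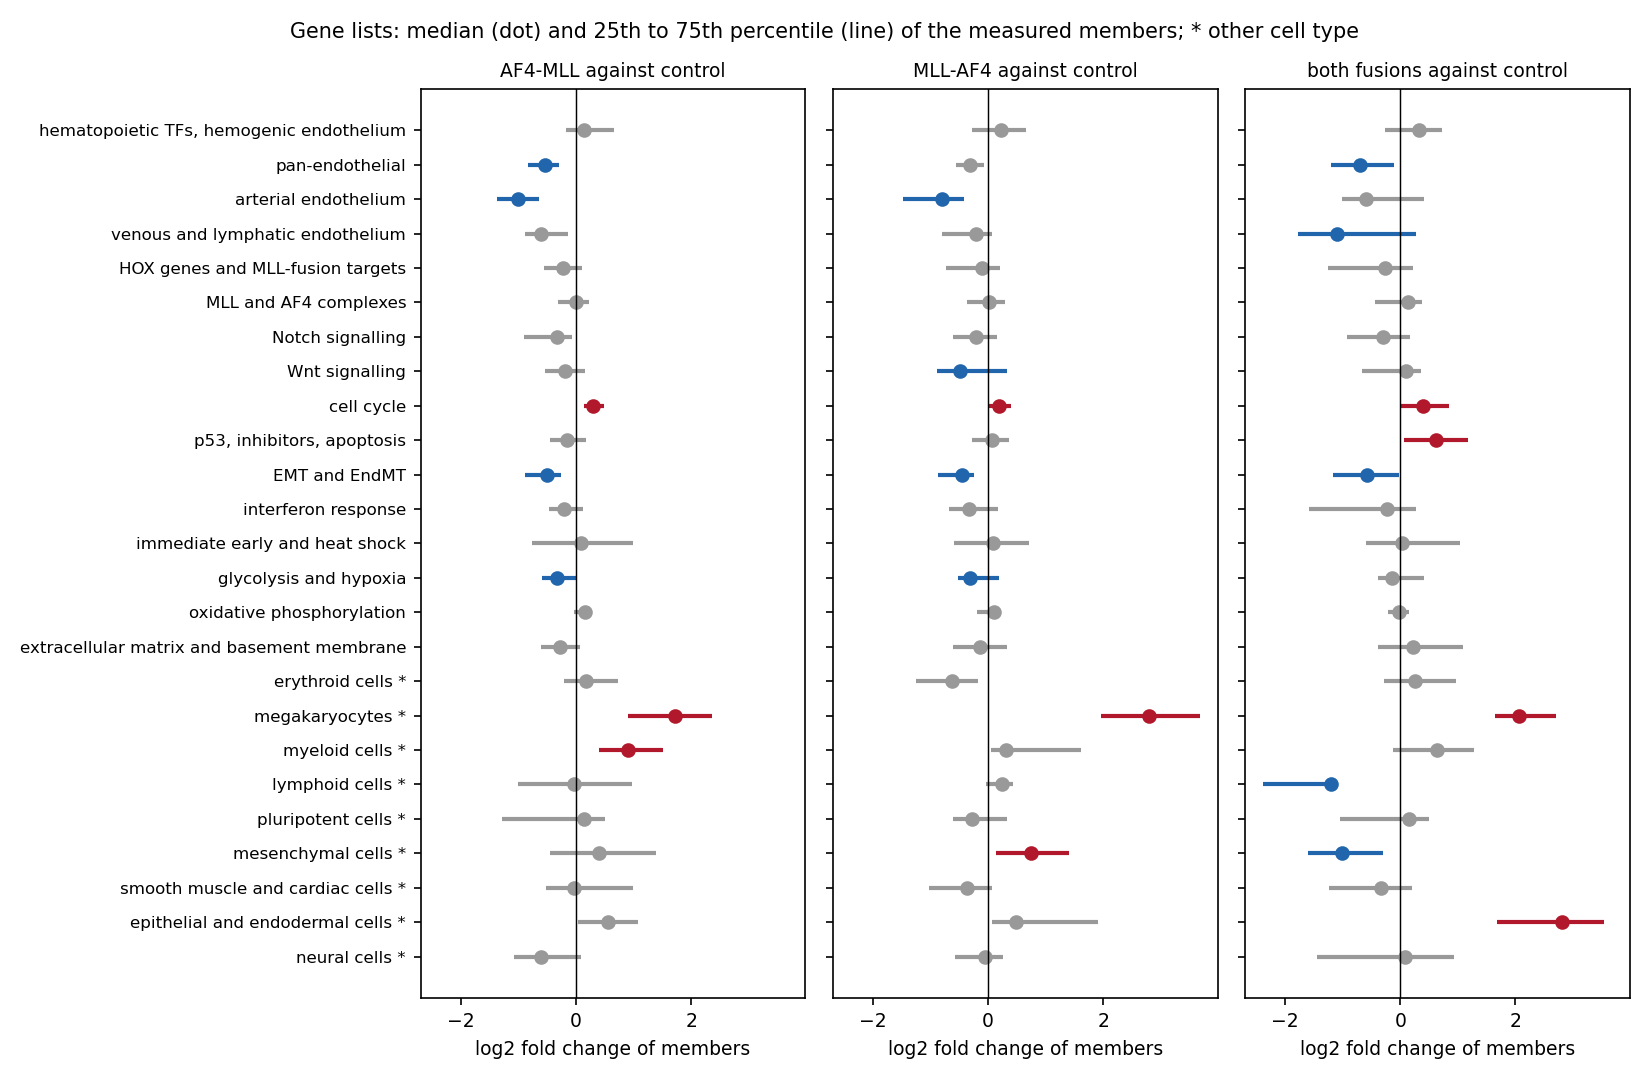
Median log2 fold change (point) and 25th to 75th percentile (line) of the measured genes of 25 gene lists in the 3 comparisons against control, with lists that camera called higher in red, lower in blue and uncalled lists in grey, and with an asterisk for markers of other cell types. Megakaryocyte markers lie above 0 in all 3 comparisons, with medians of 1.72 (AF4-MLL), 2.80 (MLL-AF4) and 2.06 (both fusions). Epithelial and endodermal markers were called with both fusions alone, at a median of 2.81.

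The comparison of AF4-MLL with control asked what this fusion alone changed. MEG3 (ENSG00000214548, chromosome 14), a maternally expressed imprinted long noncoding RNA, rose from 0.904 ± 0.618 to 203 ± 91.0 CPM, a log2 fold change of 7.67 (SE 0.608, adjusted p = 6.79e-05), and 8 genes fell. The log2 fold change was -5.73 (SE 0.544) for EYA4, -4.42 (SE 0.448) for EPB41L4A (ENSG00000129595, chromosome 5) and -4.05 (SE 0.431) for TMEM135 (ENSG00000166575, chromosome 11), each with an adjusted p of 0.000716. CIT (ENSG00000122966, chromosome 12), citron kinase of cytokinesis, fell by 4.03 (adjusted p = 0.0048), and CRYZ (ENSG00000116791, chromosome 1), a quinone reductase, fell from 57.1 ± 12.5 to 5.47 ± 2.38 CPM, a log2 fold change of -3.39 (SE 0.445, adjusted p = 0.0048). The same edgeR test called 523 genes (3.63%) without adjustment, and replicates did not overlap in 10.1% of all genes, where chance gives 10%. The count of 9 was 5 without AF4-MLL replicate 2 and 4 without replicate 3, where CIT (adjusted p = 0.0671 and 0.0722) and CRYZ (0.0613 and 0.0711) were no longer called. It was 38 with DESeq2 and 11 with limma-voom.

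In this comparison camera called 3 lists higher and 4 lower, none with an estimated correlation (adjusted p = 0.845 for each of the 7) or with fry, and no member of any of them passed over all genes. Megakaryocyte markers were higher in 13 of 15 (median 1.72, none passing when adjusted over the list alone, camera adjusted p = 8.46e-05). PPBP stood at 5.68 (SE 1.72, adjusted p = 1) and SELP at 2.70 (SE 0.988, adjusted p = 1), and the list stayed called in all 6 fits that left out 1 replicate. The megakaryocyte list summed to 1758, 6832 and 3633 CPM in AF4-MLL replicates 1, 2 and 3, against 945, 1686 and 1755 CPM in control. AF4-MLL replicate 1 was thus level with the highest control replicate. Cell cycle genes were higher in 38 of 40 (median 0.29, camera adjusted p = 8.3e-05). CDT1, a replication licensing factor, stood at 0.97 (SE 0.441, adjusted p = 1) and CDKN3 at 0.93 (SE 0.436, adjusted p = 1). Arterial genes were lower in 19 of 20 (median -0.996, 1 fell when adjusted over the list alone, camera adjusted p = 0.000734). DEPP1 stood at -3.27 (SE 0.801, adjusted p = 0.637) and VEGFC, a lymphangiogenic growth factor, at -2.84 (SE 1.04, adjusted p = 1). Pan-endothelial genes were lower in 30 of 33 (median -0.53, camera adjusted p = 0.00669). EGFL7 stood at -0.69 (SE 0.315, adjusted p = 1) and SOX7 at -1.09 (SE 0.521, adjusted p = 1). Myeloid markers were higher in 13 of 16 (median 0.90, camera adjusted p = 0.0268), while transition genes (median -0.51, camera adjusted p = 0.0167) were lower in 21 of 24 and glycolysis and hypoxia genes (median -0.33, camera adjusted p = 0.034) in 19 of 27. No member of the cell cycle, pan-endothelial, myeloid, transition or glycolysis list passed when adjusted over the list alone. In control replicates 1, 2 and 3 the arterial list summed to 1626, 1147 and 5056 CPM, the pan-endothelial list to 6523, 4711 and 13680 CPM and the cell cycle list to 5072, 7555 and 2719 CPM. Control replicate 3 decided several calls: without it 2 lists were called, and the cell cycle (adjusted p = 0.573), arterial (0.504), pan-endothelial (0.918, with the direction turned), glycolysis and myeloid calls ended. The pan-endothelial call also ended without AF4-MLL replicate 2, the transition call without AF4-MLL replicate 3 or control replicate 1 (0.195), the glycolysis call without AF4-MLL replicate 1 or control replicate 2 (0.476), and the myeloid call without AF4-MLL replicate 3 or control replicate 1 (0.256). Without control replicate 3, VEGFC stood at -1.004, SOX7 at -0.6477, EGFL7 at -0.4353 and CDKN3 at 0.56, and without control replicate 2, SELP stood at 4.346. The other 18 lists had adjusted p values of 0.133 to 0.904.

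The comparison of MLL-AF4 with control asked the same of the other fusion. MEG3 rose to 89.8 ± 37.2 CPM, a log2 fold change of 6.50 (SE 0.584, adjusted p = 0.000344), and 7 genes fell. The log2 fold change was -6.83 (SE 0.575, adjusted p = 0.000379) for EYA4, -4.04 (adjusted p = 0.000914) for TMEM135, -3.87 (adjusted p = 0.00115) for EPB41L4A and -3.84 (adjusted p = 0.00656) for CIT. CSTPP1 (ENSG00000149179, chromosome 11) fell from 444 ± 241 to 54.7 ± 10.3 CPM, a log2 fold change of -3.02 (SE 0.420, adjusted p = 0.00808). Without adjustment, edgeR called 552 genes (3.83%), and replicates did not overlap in 12% of all genes, where chance gives 10%. The count of 8 was 4 without MLL-AF4 replicate 1, 4 without replicate 2 and 5 without replicate 3, where CSTPP1 (adjusted p = 0.0873, 0.0921 and 0.124) was not called, nor was CIT without replicate 1 (0.0537) or 2 (0.0921). It was 61 with DESeq2 and 8 with limma-voom, which did not call MEG3 (adjusted p = 0.0519).

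Megakaryocyte markers were higher with MLL-AF4 in 13 of 15 measured genes (median 2.80), with none passing over all genes and 9 that rose when adjusted over the list alone (camera adjusted p = 1.18e-09, adjusted p = 0.579 with an estimated correlation). CLEC1B, a platelet receptor, stood at 4.16 (SE 1.05, adjusted p = 0.572) and PPBP at 7.14 (SE 1.83, adjusted p = 0.609), and the list stayed called in all 6 fits that left out 1 replicate. Of the list's 16 genes, ITGB3, THBS1, SELP and VWF also stand in endothelial or matrix lists. The megakaryocyte list summed to 2553, 9189 and 13890 CPM in MLL-AF4 replicates 1, 2 and 3, against 945 to 1755 CPM in control. Erythroid (3090, 8256 and 14040 CPM) and myeloid (529.1, 1545 and 1741 CPM) markers rose in the same replicate order. Mesenchymal markers were higher in 12 of 16 (median 0.74, none passing over all genes or when adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.913 with an estimated correlation). The collagen gene COL6A3 stood at 2.45 (SE 0.775, adjusted p = 0.914) and COL1A1 at 2.37 (SE 1.09, adjusted p = 0.999). Arterial genes were lower in 17 of 20 (median -0.81, camera adjusted p = 0.0142). DEPP1 stood at -2.56 (SE 0.773, adjusted p = 0.880) and HEY1, a Notch target, at -2.14 (SE 0.916, adjusted p = 0.999). Cell cycle genes were higher in 30 of 40 (median 0.19, camera adjusted p = 0.0266). UBE2C stood at 0.63 (SE 0.364, adjusted p = 0.999) and AURKB, a mitotic kinase, at 0.77 (SE 0.511, adjusted p = 0.999). Wnt signalling (median -0.49, camera adjusted p = 0.0464, adjusted p = 0.579 with an estimated correlation), transition (median -0.45, camera adjusted p = 0.0355) and glycolysis genes (median -0.32, camera adjusted p = 0.0334) were lower in 18 of 26, 21 of 24 and 19 of 27. The arterial, cell cycle, transition and glycolysis calls had an adjusted p of 0.913 with an estimated correlation, and none of these 5 lists had a member that passed over all genes or when adjusted over the list alone. Without control replicate 3 the arterial (0.876), glycolysis and cell cycle calls ended, the last with its direction turned (0.397), and without control replicate 2 the glycolysis, Wnt and mesenchymal (0.0519) calls ended. Without control replicate 1 the Wnt (0.258) and transition (0.397) calls ended, and without MLL-AF4 replicate 1 that of glycolysis (0.543). MLL-AF4 replicate 2 also decided the arterial, Wnt, cell cycle and transition calls, and replicate 3 the Wnt, cell cycle and transition calls. Without control replicate 3, whose arterial level was 5056 CPM against 1626 and 1147 CPM in replicates 1 and 2, HEY1 stood at -0.1838, DEPP1 at -1.613 and AURKB at 0.2919. AURKB stood at 0.507 without MLL-AF4 replicate 3, and UBE2C at 0.3733 without MLL-AF4 replicate 3, 0.955 without MLL-AF4 replicate 1 and 1.042 without control replicate 2. The number of called lists was 4 without MLL-AF4 replicate 2, against 7, and fry called 0. The other 18 lists had adjusted p values of 0.0814 to 0.808.

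EPB41L4A, EYA4, HIF1A, CIT, CSTPP1, TMEM135 and CAMTA1 fell in all 3 comparisons against control, where 0.0189 shared falls at most were expected between 2 of the comparisons from independent lists. HIF1A encodes the oxygen-regulated subunit of hypoxia-inducible factor and CAMTA1 a transcriptional activator, and these 2 genes are named because they complete the shared set. The 3 comparisons use the same control replicates, which alone makes their fold changes correlate. Across genes, which are not independent replicates, the correlation of the fold changes was 0.738 between the single fusions, against 0.492 in 20 simulated draws in which the groups shared controls and differed in no gene, and 0.533 and 0.532 between both fusions and AF4-MLL or MLL-AF4, against 0.484 and 0.488. The covariance exceeded the simulated by 0.347, 0.327 and 0.338. Counts in these draws were independent between genes, so many genes that move together in a control replicate are not covered. The arterial list, for example, summed to 1626, 1147 and 5056 CPM in control replicates 1, 2 and 3. The excess therefore cannot separate a shared effect of the fusions from the shared controls. With 3 control replicates the controls could not be divided between the comparisons.

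The comparison of both fusions with AF4-MLL asked what MLL-AF4 added to it. CRYZ rose from 5.47 ± 2.38 to 48.3 ± 11.1 CPM, a log2 fold change of 3.15 (SE 0.442, adjusted p = 0.0104), near its control level of 57.1 ± 12.5 CPM, and 8 genes fell. MEG3 fell by 6.78 (SE 0.595, adjusted p = 0.000255), from 203 ± 91.0 to 1.89 ± 0.613 CPM. The log2 fold change was -5.33 (adjusted p = 0.000824) for DUSP23, -5.34 (adjusted p = 0.000969) for CAT, -5.46 (adjusted p = 0.00281) for ZNF667-AS1 and -4.89 (adjusted p = 0.00401) for CSRP1. Without adjustment edgeR called 989 genes (6.86%), and replicates did not overlap in 10.3% of all genes, where chance gives 10%. The count of 9 was 67 without both-fusions replicate 2, and it was 144 with DESeq2 and 0 with limma-voom. CRYZ lost its call without AF4-MLL replicate 2 (adjusted p = 0.0961) or 3 (0.0836) and without both-fusions replicate 3 (0.0511).

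Camera called 2 lists higher and 3 lower in this comparison. Epithelial and endodermal markers were higher in 15 of 17 (median 2.09, none passing over all genes, 5 rose when adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.444 with an estimated correlation). The p53 list was higher in 21 of 24 (median 0.86, none passing over all genes, 1 rose when adjusted over the list alone, camera adjusted p = 6.38e-05, adjusted p = 0.294 with an estimated correlation). EPCAM, an epithelial adhesion molecule, stood at 2.48 (SE 0.553, adjusted p = 0.194) and APOB at 5.01 (SE 1.35, adjusted p = 0.354). The epithelial and endodermal list summed to 303 to 969.1 CPM with AF4-MLL, a range that held both-fusions replicate 2 (790.3 CPM). BCL2L1 stood at 1.25 (SE 0.317, adjusted p = 0.288) and CDKN1A, the cell cycle inhibitor p21, at 1.93 (SE 0.568, adjusted p = 0.443). The p53 list summed to 583.4 to 861.2 CPM with AF4-MLL, a range that held both-fusions replicate 2 (854.9 CPM) and not replicates 1 (1702 CPM) and 3 (1131 CPM), which had the lowest ribosomal protein share and the higher epithelial and endodermal markers (4932 and 3791 CPM, against 790.3 CPM in replicate 2). Mesenchymal markers were lower in 14 of 16 (median -1.42, none passing over all genes, 2 fell when adjusted over the list alone, camera adjusted p = 0.000425, adjusted p = 0.392 with an estimated correlation). COL3A1 stood at -1.94 (SE 0.503, adjusted p = 0.312) and COL6A3 at -2.65 (SE 0.807, adjusted p = 0.482). These 3 lists stayed called in all 6 fits that left out 1 replicate. Venous and lymphatic genes were lower in 9 of 15 (median -0.34, none passing over all genes, 3 fell when adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.294 with an estimated correlation). TFPI2 stood at -2.79 (SE 0.506, adjusted p = 0.0917) and APLNR at -2.59 (SE 0.480, adjusted p = 0.0947). All 8 lymphoid markers were lower (median -1.14, none passing over all genes, 1 fell when adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.294 with an estimated correlation). Over its 22 genes the lymphoid list summed to 11.44 to 51.36 CPM with both fusions and 49.06 to 79.85 CPM with AF4-MLL, so the groups overlapped. The venous call ended without both-fusions replicate 2 (0.155) or AF4-MLL replicate 1, and the lymphoid call without both-fusions replicate 3 (0.199). CDKN1A stood at 1.054 without both-fusions replicate 1 and APOB at 1.752 without replicate 3. Without both-fusions replicate 2, TFPI2 (0.0181), APLNR (0.0267) and EPCAM (0.0467) were called. The number of called lists was 10 without both-fusions replicate 2 and 8 without AF4-MLL replicate 2, against 5, and fry called 0. The other 20 lists had adjusted p values of 0.111 to 0.900.

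The comparison of both fusions with MLL-AF4 asked what AF4-MLL added to it. With both fusions 0 genes rose and 12 fell. The log2 fold change was -5.60 (SE 0.574) for MEG3 and -4.72 (SE 0.492) for S100A6, each with an adjusted p of 0.0011. It was -5.09 (adjusted p = 0.00131) for DUSP23, -5.03 (adjusted p = 0.00178) for CAT, -5.54 (adjusted p = 0.00237) for ZNF667-AS1 and -3.21 (SE 0.513, adjusted p = 0.0298) for TFPI2. S100A6, CAT, CSRP1, GBP4 (an interferon-inducible GTPase), ARMCX1, DUSP23 and ZNF667-AS1 fell with both fusions against all 3 other groups. GBP4 and ARMCX1 are named because they complete this set, in which ZNF667-AS1 was counted without its strand. Without adjustment edgeR called 1065 genes (7.39%), and replicates did not overlap in 13% of all genes, where chance gives 10%. The count of 0 rises and 12 falls was 92 genes without both-fusions replicate 2, 6 without both-fusions replicate 3 and 7 without MLL-AF4 replicate 1, and it was 169 with DESeq2 and 0 with limma-voom. TFPI2 lost its call without MLL-AF4 replicate 1 (adjusted p = 0.124) or 3 (0.0772) and without both-fusions replicate 1 (0.133) or 3 (0.188).

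Mesenchymal markers were lower with both fusions than with MLL-AF4 in 14 of 16 (median -1.80, none passing over all genes, 6 fell when adjusted over the list alone, camera adjusted p = 3.45e-06, adjusted p = 0.190 with an estimated correlation). COL3A1 stood at -2.60 (SE 0.515, adjusted p = 0.115) and COL6A3 at -3.48 (SE 0.828, adjusted p = 0.249). All 8 lymphoid markers were lower (median -1.54, none passing over all genes, 1 fell when adjusted over the list alone, camera adjusted p = 0.000662, adjusted p = 0.190 with an estimated correlation, fry adjusted p = 0.0215). IL7R stood at -5.72 (SE 1.43, adjusted p = 0.294) and CD79B at -1.23 (SE 0.590, adjusted p = 0.687). Levels were low: over its 22 genes the lymphoid list summed to 11.44 to 51.36 CPM with both fusions and 93.15 to 121.8 CPM with MLL-AF4. The mesenchymal and lymphoid lists stayed called in all 6 fits that left out 1 replicate. In the venous and lymphatic list TFPI2 fell, and 5 genes fell when adjusted over the list alone (11 of 15 lower, median -0.51, camera adjusted p = 0.00496, adjusted p = 0.190 with an estimated correlation, fry adjusted p = 0.0191). Pan-endothelial genes were lower in 26 of 33 (median -0.48, camera adjusted p = 0.00718, adjusted p = 0.929 with an estimated correlation), and megakaryocyte markers in 14 of 15 (median -0.64, camera adjusted p = 0.00642, adjusted p = 0.669 with an estimated correlation). Neither had a member that passed over all genes or when adjusted over the list alone. Epithelial and endodermal markers were higher in 15 of 17 (median 1.62, none passing over all genes, 3 rose when adjusted over the list alone, camera adjusted p = 0.000662, adjusted p = 0.669 with an estimated correlation). EPCAM stood at 2.37 (SE 0.548, adjusted p = 0.232) and HNF4A at 5.65 (SE 1.52, adjusted p = 0.345). The epithelial and endodermal list summed to 2390, 408 and 547.7 CPM in MLL-AF4 replicates 1, 2 and 3, a range that held both-fusions replicate 2 (790.3 CPM). The p53 list was higher in 20 of 24 (median 0.65, none passing over all genes or when adjusted over the list alone, camera adjusted p = 0.000662, adjusted p = 0.259 with an estimated correlation). CDKN1A stood at 1.75 (SE 0.562, adjusted p = 0.464) and BCL2L1 at 0.96 (SE 0.312, adjusted p = 0.483). With MLL-AF4 the p53 list summed to 697.8 to 888.9 CPM, which again held both-fusions replicate 2 and not replicates 1 and 3, those with the higher endodermal markers and the lowest ribosomal protein share. Without both-fusions replicate 2 the venous (0.0784) and pan-endothelial (0.926) calls ended, and without both-fusions replicate 1 the p53 (0.123), megakaryocyte (0.593) and endodermal (0.0901) calls. The pan-endothelial call also ended without MLL-AF4 replicate 1, the megakaryocyte call without MLL-AF4 replicate 3 and the endodermal call without MLL-AF4 replicate 2. CDKN1A stood at 0.8723 without both-fusions replicate 1 and CD79B at -0.8064 without replicate 3. COL6A3 and EPCAM gained a call without both-fusions replicate 2 (0.0463 each). The other 18 lists had adjusted p values of 0.150 to 0.893.

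The comparison of MLL-AF4 with AF4-MLL set the reciprocal fusions against each other. In edgeR 0 of 14408 genes passed, as in DESeq2 and limma-voom (0 each), and 129 (0.895%) had an unadjusted p under 0.05. Replicates did not overlap in 9.4% of genes, where chance gives 10%. Erythroid markers were lower with MLL-AF4 in 18 of 22 (median -1.22, camera adjusted p = 0.00258), with HEMGN, a nuclear protein of blood cells, at 2.54 (SE 1.5, adjusted p = 1) and TFRC, the transferrin receptor, at -0.996 (SE 0.606, adjusted p = 1). Megakaryocyte markers were higher in all 15 (median 1.08, camera adjusted p = 0.0209). CLEC1B stood at 1.60 (SE 0.939, adjusted p = 1) and GP9, a platelet glycoprotein, at 1.98 (SE 1.24, adjusted p = 1). No member of either list passed over all genes or when adjusted over the list alone, and the adjusted p was 0.907 for each with an estimated correlation. The erythroid call ended without MLL-AF4 replicate 1 (0.497), and the megakaryocyte call without MLL-AF4 replicate 2 or 3 or AF4-MLL replicate 1 (0.384). In replicates 1, 2 and 3 the erythroid list summed to 16850, 10400 and 36660 CPM with AF4-MLL. With MLL-AF4 it summed to 3090, 8256 and 14040 CPM, so the groups overlapped. AF4-MLL replicate 3 held the fewest counts of all replicates (1345580). Without AF4-MLL replicate 2, HEMGN stood at 4.587 and GP9 at 3.004, and without MLL-AF4 replicate 3, GP9 stood at 1.318. The other 23 lists had adjusted p values of 0.0912 to 0.970. The number of called lists was 1 without MLL-AF4 replicate 1, 5 without replicate 2, 6 without replicate 3 and 5 without AF4-MLL replicate 3, against 2.

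The interaction of the 2 fusions asked whether the change with both differed from the sum of the single changes on the log2 scale. It passed for 9 genes, 4 positive and 5 negative. MEG3 had the value farthest from 0, at -13.27 (SE 0.834, adjusted p = 3.18e-06), with mean levels of 0.904, 203, 89.8 and 1.89 CPM in control, AF4-MLL, MLL-AF4 and both fusions. DUSP23 was at -6.17 (SE 0.704, adjusted p = 0.00326), ZNF667-AS1 at -5.77 (SE 0.822, adjusted p = 0.0106), CAT at -5.18 (SE 0.722, adjusted p = 0.00957) and S100A6 at -5.03 (SE 0.624, adjusted p = 0.00445), genes that fell with both fusions and passed against control with neither fusion alone. EPB41L4A (4.98, SE 0.591, adjusted p = 0.00346), CIT (4.45, SE 0.687, adjusted p = 0.0226) and TMEM135 (4.30, SE 0.567, adjusted p = 0.00599) were low with each fusion and with both. A gene high in control and about equally low in every fusion group gives such a positive value by arithmetic. The values of these genes therefore do not separate fusion effects that do not add from a difference of the control line. CRYZ (4.51, SE 0.594, adjusted p = 0.00599) was low with AF4-MLL and stood at 48.3 CPM with both fusions. It was also lower with MLL-AF4 than in control, without a call, which adds to the interaction value. Without adjustment edgeR called 837 genes (5.81%). The count of 9 was 72 without both-fusions replicate 2, 95 with DESeq2 and 3 with limma-voom. CIT lost its call without control replicate 1 (adjusted p = 0.0615), AF4-MLL replicate 1 (0.0630), 2 (0.136) or 3 (0.144), or MLL-AF4 replicate 1 (0.0560) or 2 (0.132), and ZNF667-AS1 without control replicate 1 (0.0517), AF4-MLL replicate 2 (0.0515) or MLL-AF4 replicate 2 (0.0506).

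Among the lists, the interaction was negative for megakaryocyte markers in 14 of 15 genes (median -2.28, none passing over all genes or when adjusted over the list alone, camera adjusted p = 6.72e-06). PPBP stood at -6.73 (SE 2.17, adjusted p = 0.638) and CLEC1B at -3.20 (SE 1.34, adjusted p = 0.783). It was negative for mesenchymal markers in 13 of 16 (median -1.80, none passing over all genes, 7 fell when adjusted over the list alone, camera adjusted p = 1.31e-05). COL6A3 stood at -5.10 (SE 1.12, adjusted p = 0.249) and COL3A1 at -2.88 (SE 0.699, adjusted p = 0.326). These 2 lists stayed called in all 12 fits that left out 1 replicate, each with an adjusted p of 0.417 with an estimated correlation. Arterial genes were positive in 19 of 20 (median 1.43, none passing over all genes, 4 rose when adjusted over the list alone, camera adjusted p = 0.00623, adjusted p = 0.808 with an estimated correlation). DEPP1 stood at 4.89 (SE 1.09, adjusted p = 0.273) and ALPL at 8.08 (SE 2.52, adjusted p = 0.630). The arterial list summed to 4257, 589.8 and 2397 CPM in both-fusions replicates 1, 2 and 3, of which replicates 1 and 3 had the lowest ribosomal protein share and the higher endodermal markers (4932 and 3791 CPM). It summed to 1147 to 5056 CPM in control, 1100 to 1342 CPM with AF4-MLL and 1218 to 1720 CPM with MLL-AF4. The p53 list was positive in 20 of 24 (median 0.85, camera adjusted p = 0.00197, adjusted p = 0.417 with an estimated correlation). CDKN1A stood at 2.53 (SE 0.787, adjusted p = 0.630) and GADD45B at 2.25 (SE 0.911, adjusted p = 0.773). The summed p53 list was above every control replicate (up to 877.9 CPM) in both-fusions replicates 1 and 3 (1702 and 1131 CPM), the replicates with the lowest ribosomal protein share, and not in replicate 2 (854.9 CPM). Glycolysis genes were positive in 23 of 27 (median 0.43, camera adjusted p = 0.00785, adjusted p = 0.808 with an estimated correlation). Myeloid markers were negative in 14 of 16 (median -1.05, camera adjusted p = 0.0292, adjusted p = 0.808 with an estimated correlation), and lymphoid markers in 8 of 8 (median -0.86, 1 fell when adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.417 with an estimated correlation). No member of these 4 lists passed over all genes. The arterial call ended without control replicate 3 (0.216) or both-fusions replicate 1 or 3, the p53 call without both-fusions replicate 1 (0.0700), and the lymphoid call without control replicate 1 (0.0600), MLL-AF4 replicate 3 or both-fusions replicate 3. The glycolysis call ended without control replicate 2, AF4-MLL replicate 1, MLL-AF4 replicate 1 or both-fusions replicate 2 (0.128), and the myeloid call without control replicate 1, AF4-MLL replicate 3, MLL-AF4 replicate 3 or both-fusions replicate 1 (0.421). DEPP1 (0.015), PPBP (0.0336, at -11.2) and COL6A3 (0.0429) gained a call without both-fusions replicate 2, while CDKN1A stood at 1.648 and GADD45B at 1.231 without both-fusions replicate 1. Myeloid markers summed to 267.1, 2434 and 600.2 CPM in both-fusions replicates 1, 2 and 3. The number of called lists was 4 without both-fusions replicate 1, against 7, and fry called 0. The other 18 lists had adjusted p values of 0.0616 to 0.802. In each of the 7 contrasts, the median, mean and test of every called list had the same sign.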

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

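The tests of other cell types, of poor libraries, of dilution, of changes of a line and of mislabelling, and the values of DLK1, DIO3, DIO3OS and WDR25, were chosen after the result was seen, while the tests of depth, of the maternally expressed neighbours of MEG3 and of other splits were set before it.

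The 50 most abundant genes took 17.7% of counts in the repeat 1 library of control replicate 3, against 20.1% in the nearest control library, and 29.15% in the repeat 3 library of AF4-MLL replicate 3, against 25.41% in the nearest library of that group. These were 2 of 28 such tests of a library far from its group, and chance gives about 1 in 20. The interaction test found that the change with both fusions differed from the sum of the single changes for MEG3 (-13.27), DUSP23 (-6.17), ZNF667-AS1 (-5.771), CAT (-5.182), S100A6 (-5.028), EPB41L4A (4.981), CRYZ (4.505), CIT (4.455) and TMEM135 (4.3), as log2 values.

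EPB41L4A, EYA4, HIF1A, CIT, CSTPP1, TMEM135 and CAMTA1 were high in control and low in all 3 fusion groups. After counts were thinned to the smallest replicate total, all 7 were still called in all 3 comparisons, which argues against sequencing depth. Lists of other cell types were higher in control than with the single fusions by at most 0.331 on the log2 scale (neural markers). This is the mean of the AF4-MLL and MLL-AF4 medians. It lay far below the falls of the 7 genes, which argues against the listed cell types in the control sort. The test did not cover cell types outside the lists or the both-fusions group, and the 7 genes were picked for their falls. Of the 7 genes, 0 were called between any fusion groups, as a difference of the control line unrelated to the fusions would give. No call does not show equal levels, since 42% of simulated 4-fold changes were found. EYA4 held 0 counts with both fusions, against log2 values of -5.73 with AF4-MLL and -6.83 with MLL-AF4 against control. A difference of the control line cannot be told apart from an effect of either fusion, since the labels name no separate lines within a condition. Part of the agreement between the comparisons may also come from the shared controls.

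S100A6, CAT, CSRP1, GBP4, ARMCX1, DUSP23 and ZNF667-AS1 (an antisense gene, counted without its strand) were low with both fusions alone. After thinning, 6 of the 7 were still called against all 3 other groups, which argues against depth, and without libraries under 13000 genes detected, a setting that took out 4 both-fusions libraries and left 2 both-fusions replicates, 7 of the 7 were 4-fold or more lower than in all 3 other groups, which argues against poor libraries. Dilution of endothelial cells by cells of another type would lower the endothelial genes alike. The 25th percentile of the pan-endothelial changes was -1.2, against a smallest fall of -2.87 in the set. These values speak to dilution of endothelial cells alone. The 7 genes were picked for their falls in these data, and loss of another cell type is not covered. Of the 7 genes, 0 were called with a single fusion, as a change of the both-fusions cells unrelated to the fusions would give. This cannot be told apart from the joint action of the fusions, since the labels name no separate lines within the both-fusions group.

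MEG3 was high with each fusion alone and low in control and with both fusions. All 18 single-fusion libraries held more MEG3 CPM than every other library (lowest 35.7, highest other 6.39). This argues against a single-fusion library mislabelled as control or both fusions, or the reverse. A swap of AF4-MLL with MLL-AF4 libraries, or of control with both-fusions libraries, would not show. Of the maternally expressed neighbours of MEG3, MEG9 lay below the filter, and 1, MEG8, was higher in both single-fusion groups than in control at an unadjusted p under 0.05, with log2 values of 3.35 (SE 1.05, edgeR adjusted p = 1) and 2.58 (SE 1.02, edgeR adjusted p = 0.999). With both fusions MEG8 stood at -5.41 (SE 1.25, edgeR adjusted p = 0.203) against AF4-MLL and -4.64 (SE 1.23, edgeR adjusted p = 0.343) against MLL-AF4, in the direction of MEG3. Other measured genes of the region stood nearer 0 with AF4-MLL and MLL-AF4 against control. The log2 values were -0.61 and -0.06 for DLK1, -0.82 and 0.21 for DIO3, 0.09 and -0.34 for DIO3OS, and -0.30 and -0.28 for WDR25. DIO3OS is an opposite-strand gene, counted without its strand. A change of the maternally expressed genes of the region is a candidate explanation that rests on MEG8 alone. It was not shown for the region as a whole, and its origin, in the fusions or in the history of the lines, is untested.

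Splits of the 6 replicates of 2 groups that ignore the labels number 10, too few for a share under 0.05. For both fusions against control, the real split gave 38 genes and the highest other 45, so that 2 of 10 splits gave as many. The higher split set control replicates 1 and 2 and both-fusions replicate 2 against control replicate 3 and both-fusions replicates 1 and 3. The latter were those with the fewest genes detected (17315, 15871 and 17915). They also had the highest arterial sums (5056, 4257 and 2397 CPM) and the lowest erythroid sums (4494, 1716 and 1470 CPM) of the 6 replicates. This points to a structure of the samples, in which library quality and cell content cannot be told apart. The real and highest other counts were 9 and 0 for AF4-MLL against control (1 of 10), 8 and 0 for MLL-AF4 against control (1 of 10), 9 and 0 for both fusions against AF4-MLL (1 of 10), 12 and 0 for both fusions against MLL-AF4 (1 of 10) and 0 and 0 for MLL-AF4 against AF4-MLL (10 of 10). For the interaction, 3 of 100 regroupings of the 12 replicates, the real groups included, gave 9 genes or more. The highest other regrouping gave 273 genes. These regroupings mix all groups, so they ask whether the groups differ at all. They cannot decide whether chance gave the 9 interaction genes. Which replicates the regrouping with 273 genes set together was not recorded, so no structure of the samples can be read from it.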

How the results depend on the processing

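The setting without libraries under 13000 genes detected and the list tests that leave out 1 replicate were chosen after the data were seen. Counts of changed genes are given in the order both fusions against control, AF4-MLL against control, MLL-AF4 against control, both fusions against AF4-MLL, both fusions against MLL-AF4, MLL-AF4 against AF4-MLL and the interaction, where the reported counts were 38, 9, 8, 9, 12, 0 and 9. With 3 replicates per group, 2.8% of 2-fold changes simulated in the more abundant genes were found. Library depth differed 15.6-fold, and after every replicate was thinned to 1345580 counts, both fusions against control gave 31 changed genes among 11246 tested. In 18 pairs of replicates with the same number, correlations of the deviations from their group ran from -0.0871 to 0.254, with 11 over 0.1. Their median was 0.139, against -0.0632 for pairs with other numbers, and 9 of 12 replicates correlated best with their own number. This is a hint of pairing from the data and not from the design, and since not every pair lay over 0.1, the numbers were not used as pairs. The sample number as a block gave 49, 10, 10, 10, 13, 0 and 13 genes.

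DESeq2 gave 423, 38, 61, 144, 169, 0 and 95 genes, and limma-voom 15, 11, 8, 0, 0, 0 and 3. No low-count filter gave 531, 115, 171, 256, 304, 23 and 233, and the 36 libraries as separate samples, which overstates n if the libraries of a sample are not independent, gave 278, 24, 65, 108, 128, 0 and 88. The sample number as a random effect gave 82, 16, 72, 18, 56, 0 and 48, and sums by repeat number 477, 40, 116, 92, 121, 0 and 105. Only the groups compared gave 1, 12, 9, 5, 3 and 0. Without libraries under 13000 genes detected, which left 2 both-fusions replicates, the counts were 24, 10, 12, 12, 11, 0 and 12, of which 19, 9, 8, 9, 9, 0 and 8 were among the reported genes. The cause of these differences was not tested. With only the groups compared in the fit, the counts fell in the comparisons that hold both fusions and in no other. DESeq2 size factors, upper-quartile factors, the filter of 10 CPM, the block and leaving out libraries under 0.2 of the median total kept every count within 1.5 times of the reported. Leaving out 1 replicate gave 17 to 127, 4 to 10, 4 to 10, 6 to 67, 6 to 92, 0 to 0 and 7 to 72, with the highest value without both-fusions replicate 2 where both fusions were compared.

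For gene lists, where 9, 7, 7, 5, 7, 2 and 7 were called, an estimated correlation gave 0 in all, and fry 1, 0, 0, 0, 2, 0 and 0. Without libraries under 13000 genes detected the interaction had 3 called lists. Leaving out 1 replicate gave 5 to 11, 2 to 8, 4 to 8, 4 to 10, 5 to 9, 1 to 6 and 4 to 10. Without control replicate 3 the pan-endothelial list of AF4-MLL against control turned its direction (adjusted p 1.55e-06 to 0.918 over the fits that left out 1 replicate), as did the cell cycle list of MLL-AF4 against control (2e-06 to 0.397).

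Of 2210 values of named genes other than KMT2A and AFF1 under the alternatives, 1950 kept their direction and their side of the threshold, 133 lost a call, 127 gained a call and 0 turned their sign. Of the 780 that left out 1 replicate, 57 lost a call and 13 gained a call. Limma-voom ended 30 calls, only the groups compared 24, the random effect 11 and leaving out libraries under 13000 genes detected 9. Leaving out 1 replicate, the AFF1 change with both fusions against control ran from -0.2163 to 0.7007, and those of KMT2A against control from -0.114 to 0.3792 with AF4-MLL and from -0.07685 to 0.2904 with MLL-AF4, so that their signs are not settled.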

Other observations

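The panel of imprinted genes, and the genes named from it, were chosen after MEG3 was seen, and the test of whole chromosomes was set before its result.

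Of 22 measured imprinted genes other than MEG3, 10 were higher and 12 lower with both fusions than in control, from -6.959 (NNAT) to 2.756 (PEG10) on the log2 scale, and NNAT alone passed. With AF4-MLL 9 were higher and 13 lower, and with MLL-AF4 10 and 12. DLK1, the paternally expressed neighbour of MEG3 and a Notch-related membrane protein, had a log2 fold change against control of 1.92 (SE 0.562, edgeR adjusted p = 0.226) with both fusions, -0.61 (adjusted p = 1) with AF4-MLL and -0.06 (adjusted p = 0.999) with MLL-AF4. IGF2, an imprinted growth factor of chromosome 11, stood at -2.39 (SE 0.798, adjusted p = 0.298) with both fusions. NNAT, which fell with both fusions against control, had values of -5.56 (adjusted p = 0.146) against AF4-MLL and -6.06 (adjusted p = 0.0894) against MLL-AF4.

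A hypothesis was that a line had gained or lost a whole chromosome, which would shift the median of its genes. The largest distance of a chromosome median from the median of all genes was 0.129 on the log2 scale (chromosome 5, MLL-AF4 against control), below the 0.3 set as the bound, so the test was negative for a change in all cells.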
